A study of Caenorhabditis elegans with 4 samples.

How the data were processed

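RNA-seq was made from whole young adult nematodes of 2 Caenorhabditis elegans strains, N2 and VZ1, each left unstressed on the bacterial food OP50 or exposed to 10 mM NaAs (sodium arsenite, a source of oxidative stress) for 5 h, per the labels. Total RNA was extracted with Trizol, per the labels' protocols. Each of the 4 groups has 1 library. The deposited values are 4 tables, 1 for each pair of libraries that share a strain or a condition.

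Per the submitters' processing notes, TopHat, Bowtie2, Cufflinks and the genome build ce10 were used. The versions, the read lengths, the strandedness and the gene annotation are not given in the sources used here. Per the file headers, the tables have the layout of Cuffdiff, the program of the Cufflinks package that compares 2 conditions, and give an FPKM value (fragments scaled to the length of the exons and to the number of fragments mapped) for each library of a pair. FPKM values were made by the authors for each pair on its own, with separate locus numbering, so that levels from different tables are not on exactly 1 scale. A library's FPKM in different tables could be compared for 7 genes in unstressed N2 (median ratio 1.02) and 4 genes in stressed N2 (median ratio 0.99) at the same locus, and for 0 genes in either VZ1 library. Per the file headers, the authors also deposited a p-value and a q-value, the p-value adjusted over the genes tested, for each gene.

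Each row of the 4 tables carries the authors' mark of significance, and the largest q in any of them is 0.0492, so the tables list called genes and give no value for any other gene. The number of genes tested was worked back from the authors' p- and q-values, as q times rank divided by p. It came to 14397, 14420, 14419 and 14358 genes for stress in N2, stress in VZ1, strain without stress and strain under stress. It was the same at every p-value listed in a table, which means that no gene is missing from a table up to the largest p-value it lists. Called genes with a larger p-value, if left out of a table, would not show in this check. The smallest p-value listed is 5e-05 in all 4 tables.

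Fold changes were computed from the FPKM values as log2 of stressed over unstressed, or of VZ1 over N2, with no pseudocount. The deposited fold column was not used because it holds spreadsheet error text on some rows. A gene with an FPKM of 0 in a library is called listed at 0 and was given a direction but no fold. This applies to 52 of the 393 rows. A locus to which a table gives several genes, on 30 rows in all and with some loci in more than 1 table, has 1 value per library for all of them. The tables hold 302 distinct gene names, and all 302 were found in the RefSeq gene table of assembly WBcel235, which was used only for current names, gene types and the order of genes. All coordinates are those of the tables, in ce10. Unnamed loci, 4 in all, are counted but belong to no list.

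No test was made across libraries, since each group has 1 library and no spread between replicates can be measured. A gene is said to have risen, fallen, or been higher or lower where the authors' table lists it, and the authors' test then compares 2 libraries and not 2 conditions. No read counts are in the tables used here, and the depth of the libraries is unknown. Only 39 of the 786 FPKM values lie between 0 and 1, too few to recover it, so no counting intervals or detection limits are given. Reads shared by near-identical genes can be split between them by the authors' assignment, so values of single members of the hsp-16, vitellogenin, collagen and major sperm protein families are uncertain.

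The 20 gene lists, the rule for the genes named and the alternatives in processing were fixed before the data were examined. A list's count is set beside the number that it would hold if its members were listed no more often than all genes, which is its annotated members times the genes listed divided by the genes tested. This number is an upper bound, since not every annotated member was tested. The rule names trx-1, skn-1, gst-4 and gcs-1, the 5 genes with the largest rise and the 5 with the largest fall of FPKM of at least 1 in the higher library, and up to 3 members of each list by size of fold. It also names the 5 genes with the largest mean fold among those listed in both comparisons of a pair, any of opposite direction up to 5, the 5 with the largest difference between the strains' stress responses, and up to 3 genes per comparison listed at 0. Further genes, named where a count is 5 or less and in the closing part, were chosen after their values were seen.

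The stress response of the strains was compared as the log2 fold in VZ1 minus that in N2, for the 105 genes with a value above 0 in all 4 libraries. For 73 of these both stress tables list the gene, for some, such as acdh-1, at a locus whose extent differs between the tables. For the other 32 both strain tables list it, and the stress fold is then taken across tables, at a locus whose extent differs between them for 6 genes. The alternatives were stricter limits on the fold, on FPKM and on q, a pseudocount of 1 or 0.1 FPKM, and a match of loci by at least 50% reciprocal overlap in place of names. A count without merged loci, loci wider than 50000 bp and genes listed at 0, and lists read with current gene names, were added after the data were seen. The counting, matching and list functions were tested on simulated tables of 14000 genes, where 7 of 7 known quantities were recovered. The simulated genes had 1 name and 1 locus each and no value of 0. Merged loci, repeated entries and genes at 0 were thus not covered, and the number of genes tested was recovered by construction. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and Matplotlib 3.10.9 were used.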

Results

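The data are the FPKM values of genes called by the authors in 4 pairs of RNA-seq libraries from whole young adult C. elegans. N2 is the standard wild-type strain. VZ1 is known as a strain that carries a deletion in trx-1, the gene of a thioredoxin made in a pair of sensory neurons. The series' title names TRX-1 and SKN-1, the worm's Nrf-family transcription factor of the oxidative stress response. The 4 groups (N2 unstressed, N2 stressed, VZ1 unstressed and VZ1 stressed, where stressed means 5 h in 10 mM sodium arsenite) have 1 library each. There are thus no replicates, and no difference below has a replicate check. Neither trx-1 nor skn-1 is listed in any of the 4 tables. The tables therefore hold no level of trx-1 that could check the strain labels. The depth of the libraries is unknown.

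The comparison of stressed with unstressed N2 asks which genes respond to arsenite in the wild type. Glutathione S-transferase genes, whose enzymes join glutathione to reactive compounds, led the rise. The SKN-1 target gst-4 (chromosome IV, 10142210 to 10142978) rose from 105 to 7025 FPKM, gst-38 (chromosome V, 15915223 to 15915910) from 14.01 to 3730 FPKM and gst-30 (chromosome II, 4933922 to 4935002) from 1.10 to 1238 FPKM. The small heat shock protein genes hsp-16.41 and hsp-16.2, neighbours on chromosome V, rose 76.9-fold and 59.5-fold. Of 6 yolk protein genes 5 fell, among them vit-4 from 98.9 to 0.60 FPKM and vit-2 from 186 to 28.8 FPKM. In all, 151 genes (1.05% of 14397 tested) were listed, of which 115 rose and 36 fell. The median rise was 12.1-fold and the median fall 6.89-fold.

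Of the 16 SKN-1 phase 2 targets, a list of detoxification genes known to depend on SKN-1, 11 rose and none fell, where independent placement gives at most 0.17. They include gst-7 (140 to 4404 FPKM), dhs-8, a short-chain dehydrogenase gene (2.64 to 89.996 FPKM), and sdz-8 (20.2 to 851 FPKM), whose locus also covers C55A6.3 and C55A6.6. The glutathione-synthesis gene gcs-1 was not listed. Of 47 glutathione S-transferase genes 14 rose, against at most 0.49, by a median log2 of 5.15. The list shares 9 of these 14 with the SKN-1 list. Of other detoxification enzymes, only ugt-13 of 67 UDP-glucuronosyltransferase genes (9.58 to 110 FPKM) and cyp-34A9 of 80 cytochrome P450 genes (6.16 to 29.5 FPKM) were listed, counts near the bounds of 0.70 and 0.84. The catalase gene ctl-3 (2.11 to 15.96 FPKM) was the only one of 37 redox enzyme genes listed.

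Of 16 small heat shock protein genes 4 rose, against at most 0.17. Beside hsp-16.41 (6.97 to 536 FPKM) and hsp-16.2 (7.97 to 474 FPKM) these were hsp-16.11 and hsp-16.49, both listed at 0 in unstressed animals and at 2.47 and 3.32 FPKM in stressed animals. None of 43 genes of HSP70, HSP90 and their cochaperones was listed. Metal and arsenite response genes went both ways, with 4 of 25 higher and 1 lower against at most 0.26. The arsenite-inducible gene aip-1 rose from 42.4 to 632 FPKM, the cadmium-responsive genes cdr-1 and cdr-4 rose to 38.6 and 395 FPKM, and the transporter gene mrp-7 rose to 101 FPKM. The metallothionein gene mtl-2, 4.93 kb from aip-1, fell from 1218 to 166 FPKM.

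All 5 listed vitellogenin genes, of 6 annotated, fell, and so did all 4 listed collagen genes of 217, against bounds of 0.063 and 2.28. Vitellogenins are the yolk proteins that the adult intestine makes for the oocytes. Among the vitellogenins, falls were largest for vit-4 (log2 −7.36) and vit-5 (log2 −5.08), and vit-1 fell from 29.1 to 3.83 FPKM. The cuticle collagen genes col-3 (26.02 to 0.70 FPKM), col-20 (221 to 26.01 FPKM) and col-137 (60.2 to 7.46 FPKM) fell, as did col-178. Innate immunity genes, 7 of 464, all rose, against at most 4.87. Current gene names make them 11, of which 1, the locus of F28A12.3 and F28A12.4, fell (356 to 72.6 FPKM). Among the 7 clec-143, a C-type lectin gene, rose from 0.97 to 64.0 FPKM, dod-24 from 26.6 to 1313 FPKM and dod-17 from 25.04 to 776 FPKM.

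Lipid genes were split, with 2 of 109 higher and 2 lower against at most 1.14. The fasting-induced lipase gene fil-1 rose from 5.06 to 72.7 FPKM, while the stearoyl-CoA desaturase gene fat-7 fell from 31.6 to 4.93 FPKM and the acyl-CoA dehydrogenase locus acdh-1, merged with uri-1, from 3144 to 430 FPKM. Of 460 ubiquitin-proteasome genes 2 F-box loci were listed, against at most 4.82. A count under such an upper bound does not show a shortage. The locus of fbxa-127, srz-99 and srz-100 rose from 0.36 to 4.38 FPKM and fbxa-72 fell from 66.8 to 14.1 FPKM. Outside the lists, changes included rises of W06H8.2 (1.22 to 264 FPKM), C32H11.4 (7.87 to 1245 FPKM) and the pseudogene T19D12.3 (1.45 to 208 FPKM). Falls outside the lists included R08E5.3 (156 to 4.63 FPKM) and pmp-5, a transporter gene (279 to 11.6 FPKM). The prion-like genes pqn-90 and pqn-91, 2 of 71 in their list, were listed at 0 in stressed animals and below 1 FPKM in unstressed ones. No member of the lists of molting, sperm, oocyte and germline, neuropeptide, muscle and histone genes was listed.

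In the authors' deposited table the q of gst-4, gst-38, hsp-16.41, aip-1, vit-4 and pmp-5 is 0.00735, the smallest it holds, while that of gst-30 is 0.0477. At 0 in 1 library were 24 of the 151 genes, and the highest other values among these were 372 FPKM for mir-260, given at a locus 642439 bp wide, 69.7 FPKM for an unnamed locus at 3570811 to 3571005 of chromosome X, both in unstressed animals, and 59.6 FPKM for Y75B12A.2 in stressed animals.

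The same comparison in VZ1 asks how that strain responds. The glutathione S-transferase and hsp-16 genes again led. gst-4 rose from 76.8 to 8744 FPKM, gst-38 from 13.6 to 3440 FPKM, gst-12 from 8.19 to 690 FPKM, and hsp-16.41 from 5.52 to 898 FPKM. The gene gcs-1, whose enzyme makes the first intermediate of glutathione synthesis, rose from 66.0 to 590 FPKM. R08E5.3 (149 to 2.97 FPKM), the lipase-related gene lips-6 (81.0 to 2.63 FPKM) and pmp-5 (242 to 12.2 FPKM) fell the most. Of 14420 genes tested 106 were listed, 88 higher and 18 lower, with a median rise of 14.3-fold and a median fall of 9.69-fold.

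Of the SKN-1 phase 2 targets 9 of 16 rose, and of the glutathione S-transferase genes 12 of 47, against at most 0.12 and 0.35. UDP-glucuronosyltransferase genes numbered 2 of 67, ugt-18 (0.56 to 29.01 FPKM) and ugt-13 (21.9 to 146 FPKM), against at most 0.49. Small heat shock protein genes numbered 2 of 16, hsp-16.41 and hsp-16.2 (9.65 to 769 FPKM). Of the metal and arsenite response genes 3 rose and 1 fell, with aip-1 at 39.9 and 1033 FPKM, cdr-4 at 77.7 and 547 FPKM and mtl-2 at 855 and 100.04 FPKM in unstressed and stressed animals. Innate immunity genes numbered 3 of 464, or 5 with current gene names, around the bound of 3.41. The 3 all rose, namely dod-17 (24.2 to 931 FPKM), dod-24 (57.3 to 1560 FPKM) and the infection response gene irg-3 (35.8 to 323 FPKM). The lipid genes acdh-1 (2595 to 209 FPKM, at a locus merged with C55B7.3) and fat-7 (34.8 to 3.60 FPKM) fell and fil-1 (6.998 to 86.0 FPKM) rose. fbxa-72 fell from 132 to 21.1 FPKM, the only ubiquitin-proteasome gene listed.

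No member of the vitellogenin or collagen lists was listed for stress in VZ1. The same held for the lists of cytochrome P450, redox enzyme, HSP70 and HSP90, prion-like, molting, sperm, oocyte, neuropeptide, muscle and histone genes. This covers only members of these lists, and other genes such as the flavin monooxygenase gene fmo-2 (2.58 to 20.5 FPKM) did rise. Of the 16 collagen genes whose levels in all 4 libraries are known from the separately normalised strain tables, however, 15 stood lower in stressed than in unstressed VZ1 and 16 in stressed than in unstressed N2. Among them col-178 had log2 stress folds of −2.11 in N2 and −2.06 in VZ1 and col-20 of −3.04 and −2.07. The 4 vitellogenin genes listed between the unstressed strains stood at 0.17 FPKM (vit-5) to 9.51 FPKM (vit-2) in unstressed VZ1. A fall from such levels could go uncalled. Of these 4 only vit-6 has a level in stressed VZ1, 12.6 FPKM, which is above its 6.69 FPKM without stress. Other changes included rises of W06H8.2 (3.03 to 493 FPKM) and C32H11.4 (9.25 to 1283 FPKM) and a fall of T13F3.6 (166 to 13.4 FPKM). In the authors' deposited table gst-4, hsp-16.41, aip-1 and pmp-5 have its smallest q, 0.0111, and gcs-1 has 0.0324. At 0 in 1 library were 19 of the 106 genes, with the highest other values for mir-239.2 (12.7 FPKM, stressed), Y37E3.21 (11.27 FPKM, stressed) and C30F2.6 (8.85 FPKM, unstressed, at a locus 656046 bp wide).

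Both strains' stress tables list 74 genes, 67 higher and 7 lower in each, and none in opposite directions. Independent lists would share 1.11 genes, and the comparisons have no library in common. The shared genes with the largest mean fold were gst-38 (log2 8.06 in N2 and 7.98 in VZ1), W06H8.2 (7.76 and 7.35), C32H11.4 (7.30 and 7.12), hsp-16.41 (6.26 and 7.35) and Y52E8A.3 (6.82 and 6.65). The 7 that fell in both were R08E5.3, pmp-5, T13F3.6, acdh-1, mtl-2, fat-7 and fbxa-72. Shared genes make up 49.0% of those listed in N2 and 69.8% of those listed in VZ1. A gene listed in 1 strain is not shown to respond differently in the other, since no difference was tested. For most such genes the tables give no stress fold in the other strain, the exceptions being col-3, col-20, col-178 and vit-6, whose VZ1 levels with and without stress stand in the strain tables.

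**Figure D1:**
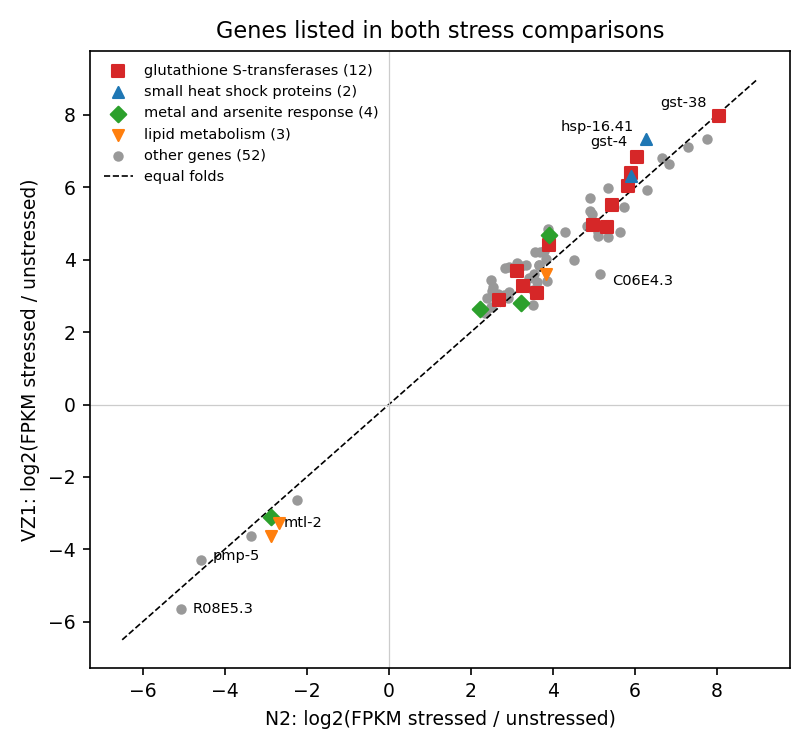
Log2 ratio of stressed to unstressed FPKM in N2 (x axis) and VZ1 (y axis) for the 73 genes listed in both stress comparisons with a value above 0 in every library, 1 point per gene and 1 library per group. The 66 rising and 7 falling genes lie along the dashed line of equal folds, with C06E4.3 (5.15 in N2, 3.59 in VZ1) farthest from it.

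For the 73 of these genes with values above 0 in all 4 libraries, the log2 stress fold in VZ1 exceeded that in N2 by a median of 0.18 (quartiles −0.29 and 0.50). The folds differed by less than 1 for 71 genes. The 2 others were C06E4.3, which rose less in VZ1 (difference −1.56), and hsp-16.41, which rose more (difference 1.08). Since the 73 genes were selected as called in both strains, the 77 listed in N2 alone and the 32 in VZ1 alone are left out. The median and the count of 71 thus cannot show how alike the responses of all genes are. The smallest absolute fold listed was also larger in VZ1 than in N2, which can raise the median. Among the 12 glutathione S-transferase genes the difference had a median of 0.13 and ranged from −0.52 for gst-39 to 0.77 for gst-4. The 3 lipid genes all had a lower log2 fold in VZ1, by −0.76 for acdh-1, −0.60 for fat-7 and −0.22 for fil-1. The acdh-1 locus is merged with uri-1 in N2 and not in VZ1, where it is merged with C55B7.3, so its 2 folds are of unlike loci. Across the 66 rising genes the folds of the strains had r = 0.93 and Spearman's rho = 0.91, a correlation across genes that are not independent replicates and were selected as called in both.

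The comparison of unstressed VZ1 with unstressed N2 asks what differs between the strains without arsenite. Cuticle collagen and vitellogenin genes were lower in VZ1. The collagen gene col-140 stood at 308 FPKM in N2 and 5.79 FPKM in VZ1, col-20 at 217 and 3.75 FPKM, and col-81 at 258 and 4.22 FPKM. The yolk protein gene vit-6 stood at 232 and 6.69 FPKM and vit-5 at 28.97 and 0.17 FPKM. Of 63 genes listed out of 14419 tested, 60 (95.2%) were lower in VZ1, by a median of 8.62-fold, and 3 were higher.

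Of 217 collagen and cuticle genes 24 were listed, all lower in VZ1, against at most 0.95. The lowest ratio among them was that of col-137 (59.9 and 0.71 FPKM, log2 −6.40). Of 6 vitellogenin genes 4 were listed, all lower, vit-2 (log2 −4.26) and vit-4 (128.6 and 2.67 FPKM) besides vit-5 and vit-6, although the vit-4 locus of this table extends beyond the gene's locus in the N2 stress table. The oocyte and eggshell genes puf-5 (35.9 and 7.002 FPKM) and cpg-2 (126 and 30.2 FPKM), 2 of 54, were lower. So were the small heat shock protein genes sip-1 (185 and 37.6 FPKM) and hsp-43 (122 and 27.9 FPKM, at a locus merged with C14F11.4), the prion-like genes pqn-63 (40.6 and 7.01 FPKM) and pqn-54 (60.3 and 12.8 FPKM) and the metalloprotease gene nas-27 (21.2 and 1.72 FPKM) of the molting list. The 3 genes higher in VZ1 were lips-6 (7.34 and 81.1 FPKM), lbp-8, a lysosomal fatty acid-binding protein gene (4.56 and 48.8 FPKM), and lips-11 (2.10 and 20.7 FPKM). Of 109 lipid genes lbp-8 was the only one listed, to which current gene names add F15E11.15, lower in VZ1.

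No member of the SKN-1, glutathione S-transferase, UDP-glucuronosyltransferase, cytochrome P450, redox, HSP70 and HSP90, metal, ubiquitin, immunity, sperm, neuropeptide, muscle or histone lists was listed between the unstressed strains, gst-4 and gcs-1 included. In the authors' deposited table the q of col-140, col-20, vit-5, vit-6 and lips-6 is 0.0141, the smallest it holds. The 2 genes at 0 in VZ1 were F12E12.1 (2.33 FPKM in N2) and F40G12.11 (0.86 FPKM in N2).

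**Figure D2:**
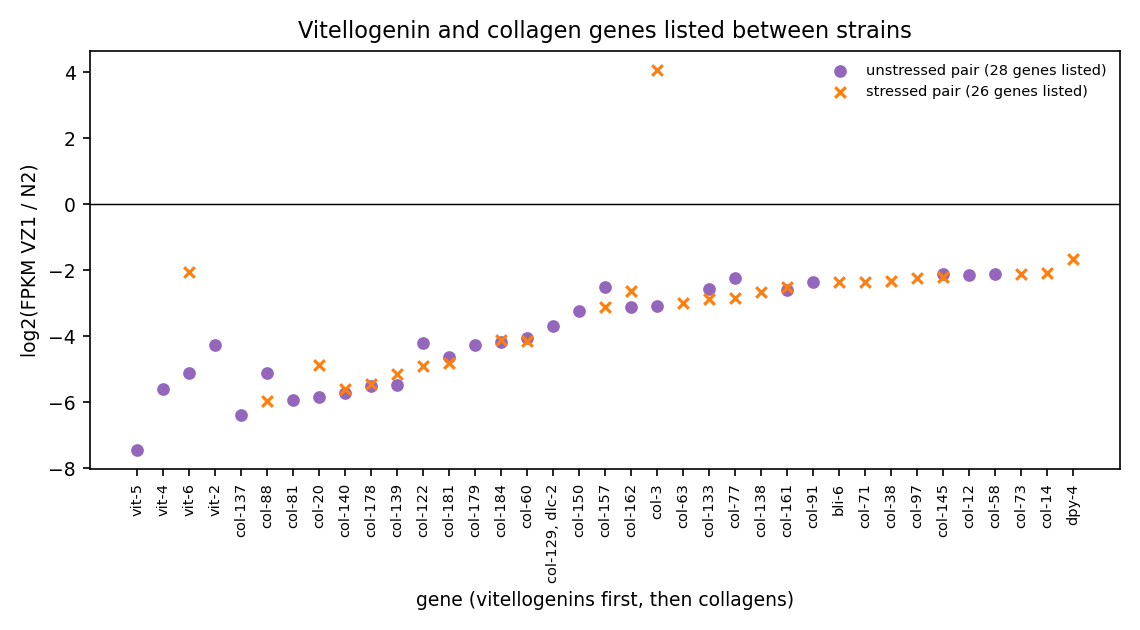
Log2 ratio of VZ1 to N2 FPKM for the vitellogenin and collagen genes listed between strains, in the unstressed pair (circles, 28 genes) and the stressed pair (crosses, 26 genes), with 1 library per group. All values lie below 0 except that of col-3 in the stressed pair (4.07).

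Under arsenite, collagen genes were again lower in VZ1 than in N2. col-88 stood at 248 FPKM in N2 and 3.95 FPKM in VZ1, col-140 at 155 and 3.18 FPKM, col-178 at 44.3 and 1.005 FPKM, col-139 at 154 and 4.33 FPKM and col-122 at 212 and 7.07 FPKM. A different collagen gene, col-3, was higher in VZ1 (0.70 and 11.8 FPKM). Of 73 entries listed out of 14358 tested, which include Y47D7A.15 at 2 entries and so cover 72 genes, 70 (95.9%) were lower in VZ1, by a median of 7.21-fold. Besides col-3, those higher were clec-9, a C-type lectin gene (2.14 and 33.9 FPKM), and lips-11 (1.89 and 17.1 FPKM).

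Of 217 collagen and cuticle genes 24 were lower and 1 higher, against at most 1.10. Of the 6 vitellogenin genes only vit-6 was listed (52.3 and 12.6 FPKM). Also lower were the major sperm protein gene msp-152 (212 and 23.6 FPKM), the only listed one of 106 sperm genes, the prion-like gene abu-12 (53.2 and 10.7 FPKM) and the hedgehog-related gene wrt-6 (121 and 26.8 FPKM). Of the molting and immunity lists, nas-21 and clec-219 were listed at 0 in VZ1 and below 1 FPKM in N2. The remaining lists, those of SKN-1 targets, detoxification, redox, heat shock, metal response, ubiquitin, oocytes, lipids, neuropeptides, muscle and histones, had no member between the stressed strains, apart from T10E9.3 in the oocyte list under its current name, and neither gst-4 nor gcs-1 was listed. In the authors' deposited table the q of col-88 and clec-9 is 0.0133, the smallest it holds, and that of col-3 is 0.0228. In VZ1 7 genes were at 0, among them R12E2.6 (13.5 FPKM in N2), F22F4.5 (1.96 FPKM) and C55C3.7 (1.75 FPKM).

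Both strain tables list 32 genes, of which 30 were lower in VZ1 in each, lips-11 was higher in each, and col-3 went opposite ways. Independent lists would share 0.32 genes, and these comparisons have no library in common. The shared genes with the largest mean ratio were col-140 (log2 −5.74 unstressed and −5.61 stressed), col-88 (−5.13 and −5.97), col-178 (−5.52 and −5.46), col-20 (−5.85 and −4.88) and col-139 (−5.48 and −5.15). The median log2 ratio of the 32 genes was −3.42 without and −3.29 with stress. Most of them were lower with stress in both strains, 25 of 32 in VZ1 (median log2 fold of the 32 genes −0.85) and 31 of 32 in N2 (median −0.80).

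The difference between the strains' stress folds was at least 1 on the log2 scale for 5 of these 32 genes, with levels taken from separately normalised tables. For col-3 it was 7.17, from 25.5 to 0.70 FPKM with stress in N2 and from 2.97 to 11.8 FPKM in VZ1. For vit-6 it was 3.06, from 232 to 52.3 FPKM in N2 and from 6.69 to 12.6 FPKM in VZ1. F54F7.3 had 1.11, F49E12.1 −1.13, and the locus of F55B11.2 and F55B11.7, whose extent differs between the tables, −1.13. With a pseudocount of 1 FPKM only 3 of the 32 differed by at least 1, namely col-3 (5.65), vit-6 (2.95) and col-20, which went from 0.97 to 1.67, while F49E12.1 (−0.18), F54F7.3 (0.88) and the F55B11.2 locus (−0.93) lay under that limit. With an FPKM of at least 1 in all 4 libraries another 3 were left, vit-6, F54F7.3 and the F55B11.2 locus, since this leaves out col-3 and F49E12.1, so that only vit-6 is in both sets.

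**Figure D3:**
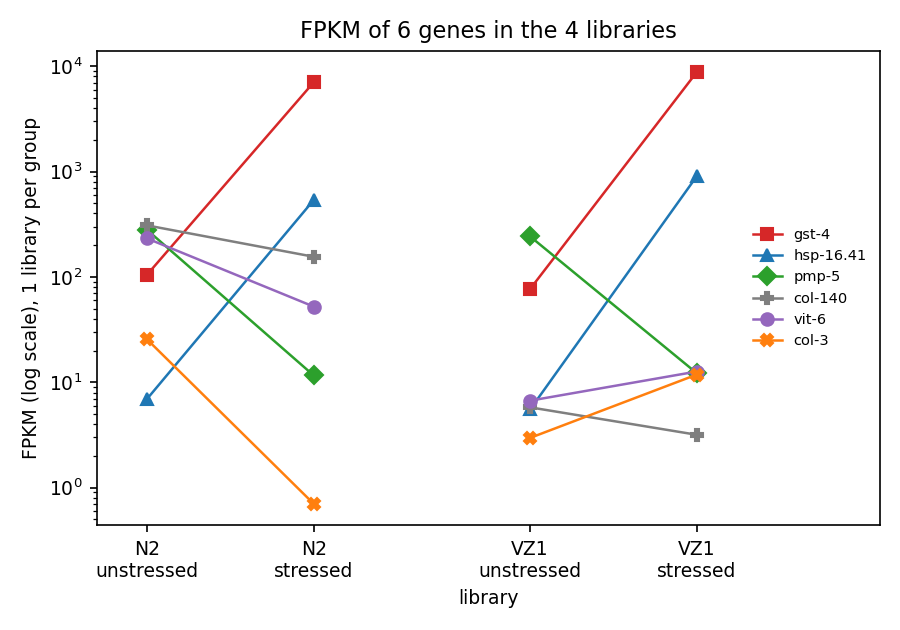
FPKM on a log scale of 6 genes in the 4 libraries, 1 library per group, with lines joining the unstressed and stressed library of a strain. gst-4 and hsp-16.41 rise and pmp-5 falls in both strains, col-140 is lower in VZ1 in both conditions, and col-3 and vit-6 are lower in the stressed than the unstressed N2 library and higher in the stressed than the unstressed VZ1 library.

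Genes that fell with stress in N2 also occurred among those lower in unstressed VZ1. The 9 genes common to these tables were col-3, col-20, col-137, col-178, vit-2, vit-4, vit-5, vit-6 and F15E11.15, and all were lower in both. Both comparisons use the unstressed N2 library, so that part or all of this overlap may come from that shared library. The N2 stress table and the stressed strain table, which use the same stressed N2 library, share 5 genes. Of these col-20, col-178 and vit-6 were lower in both, while col-3 fell with stress in N2 and was higher in stressed VZ1, and the locus of ZK792.1, ZK809.5 and ZK809.9 rose with stress in N2 (log2 3.31) and was lower in stressed VZ1 (log2 −3.63). The VZ1 stress table shares only lips-6 with the unstressed strain table (7.34 FPKM in unstressed N2, and 81.0 and 2.63 FPKM in unstressed and stressed VZ1) and no gene with the stressed one.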

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

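The limit used here, a move of more than 0.1 on the log2 scale in each strain, was chosen after the values were seen. Of the 105 genes with a value in all 4 libraries, 7 moved with arsenite in opposite directions in the strains, lower in stressed than unstressed N2 and higher in stressed than unstressed VZ1. The limit leaves out C08F11.11, with folds of 0.031 in N2 and −0.16 in VZ1, the only gene that went the other way. The shared direction of the 7 thus depends on the limit. None of these differences was tested, since each group has 1 library, and the folds join tables that were normalised separately. The difference, as the log2 stress fold in VZ1 minus that in N2, was 7.17 for the collagen gene col-3, with folds of −5.18 in N2 and 1.99 in VZ1. It was 3.06 for the yolk protein gene vit-6, with folds of −2.15 in N2 and 0.92 in VZ1. For F54F7.3 it was 1.11, with folds of −0.20 in N2 and 0.91 in VZ1. Smaller differences were those of R03G8.6 (0.80, with an FPKM of at most 0.88 in both VZ1 libraries), C02E7.7 (0.76), T10E9.3 (0.74, at a locus whose extent differs between the tables) and Y45F10C.4 (0.47). With a pseudocount of 1 FPKM the differences of col-3, vit-6 and F54F7.3 were 5.65, 2.95 and 0.88. An FPKM of at least 1 in all 4 libraries would leave out col-3, which stood at 0.70 FPKM in stressed N2, and R03G8.6. All 7 genes were lower in VZ1 than in N2 without stress, and 6 of them also with stress, col-3 being the exception. This follows from how they were chosen, since all 7 are among the 32 genes listed in both strain comparisons. Of those 32, 30 were lower in VZ1 in each. The N2 stress table itself lists col-3 and vit-6 as falling, at log2 −5.22 and −2.19, while the VZ1 stress table lists neither. No biological explanation was tested.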

How the results depend on the processing

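With 1 library per group no library could be left out, and no depth is known. No paired test was made. Libraries could be paired by strain or condition, but the spread between such pairs is the strains' difference in stress response itself. With 1 library per group it gives no replicate error. Limiting the authors' q to 0.01 left 98 genes for stress in N2 and 0 in each of the other 3 comparisons. This follows from construction, since the smallest q those tables can hold, set by the smallest p of 5e-05, is 0.0111, 0.0141 and 0.0133. All other alternatives left the 4 counts and the 2 overlaps (74 and 32 genes) within 1.5 times. The number of genes whose stress folds differ by at least 1 went from 7 to 5 with a pseudocount of 1 FPKM, with 4 of the 7 among them, and from 5 to 3 among the 32 genes of the strain tables. With all 4 values at least 1 FPKM these 5 also became 3, but col-3 was lost and only vit-6 is in both sets of 3. The N2 stress count ranged from 112 to 151 and the VZ1 stress count from 81 to 106. The strain counts ranged from 56 to 63 and from 60 to 73, and the overlaps from 68 to 74 and from 30 to 32. The lowest values of N2 stress, VZ1 stress, the stressed strains and the stress overlap came from an alternative added after the data were seen, which leaves out merged and wide loci and genes at 0. Of 35 list counts, 3 moved beyond 1.5 times with an FPKM of at least 1 in the higher library, namely the prion-like genes for stress in N2 to 0, and the immunity and the molting genes between stressed strains to 1 each. With current gene names, also added later, 4 moved, namely immunity genes to 11 for stress in N2 and 5 in VZ1, oocyte genes between stressed strains to 1 and lipid genes between unstressed strains to 2. A pseudocount of 1 FPKM moved 15 of 90 named folds by more than 1.5-fold, at most by 2.76 on the log2 scale for vit-5 between unstressed strains. None of the 215 values reversed, but a count cannot reverse, and a pseudocount cannot change the sign of a fold. Only the 5 largest differences between the strains' stress folds could have reversed, and they kept their sign with a pseudocount of 1 or 0.1 FPKM. The cause of the moves given above was not tested.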

Other observations

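Some listed genes outside the lists fixed beforehand, chosen after their values were seen and not as members of a tested group, are given here. The cystathionine beta-lyase gene cbl-1 rose from 58.8 to 328 FPKM in N2 and from 54.1 to 349 FPKM in VZ1, while cth-1, a cystathionine gamma-lyase gene, fell from 103 to 20.3 FPKM in the N2 table and is not in the VZ1 table. Its neighbour F44G3.2, now named argk-1 for arginine kinase, fell from 38.2 to 3.41 FPKM in N2. The fumarylacetoacetase gene fah-1 of tyrosine breakdown, at a locus shared with K10C2.3, rose from 203 to 2482 FPKM in N2 and from 264 to 2771 FPKM in VZ1. The ferritin gene ftn-1 rose from 8.30 to 122 FPKM and from 4.70 to 136 FPKM. The globin gene glb-1 rose from 31.8 to 1694 FPKM and from 48.3 to 2121 FPKM, and the long noncoding RNA gene tts-1 rose from 32.9 to 983 FPKM and from 44.7 to 1810 FPKM. The VZ1 table alone lists E01A2.1, now gclm-1, for the modifier subunit of the enzyme encoded by gcs-1 (60.8 to 433 FPKM), T12G3.1, now sqst-1, for the autophagy receptor p62 (40.8 to 270 FPKM), and the flavin monooxygenase gene fmo-2 (2.58 to 20.5 FPKM). The N2 table alone lists gst-30, gst-14 and sdz-8 of the SKN-1 list. Whether the strains differ in these genes was not tested, and a gene absent from a table has no value there.

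The locus of ZK792.1, ZK809.5 and ZK809.9 rose with arsenite in N2 from 47.8 to 474 FPKM and stood at 39.3 FPKM in stressed VZ1, its level in unstressed VZ1 not being listed. The lipase-related gene lips-11 was higher in VZ1 in both conditions, by log2 3.302 and 3.179, and lips-6 in the unstressed pair, by 3.47, with no value for it in stressed N2.

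All tests in the next 3 paragraphs were chosen after the result was seen. The 1st pattern is that 99 of the 103 distinct genes listed between strains were lower in VZ1 in at least 1 pair of libraries, and 5 higher, col-3 being both. A difference in scale between the libraries would lower all genes, but the 73 genes listed for stress in both strains had a median log2 ratio of VZ1 to N2 of 0.079 without stress (quartiles −0.25 and 0.47), against −3.04 for the genes listed between the unstressed strains. A loss of short transcripts from VZ1 is also argued against, since the 32 of these genes whose locus spans at most 1500 bp had a median of −0.0068 (quartiles −0.22 and 0.39). Both medians join the 2 stress tables, which were normalised separately from each other and from the strain tables. For unstressed N2 the scales of the stress and strain tables were close (median ratio 1.02 over 7 genes). For unstressed VZ1 only lips-6, at a locus of unlike extent, could be compared (ratio 0.999). A single library standing apart does not account for the 30 genes lower in both pairs, which have no library in common and would share 0.29 by independent placement, but it cannot be excluded for the 30 genes lower in the unstressed pair alone or the 39 lower in the stressed pair alone. A younger stage of the VZ1 populations, or the strain itself, may lie behind the lower collagen and yolk genes, and these cannot be told apart, since all 7 listed members of the vitellogenin, oocyte and sperm lists were lower but so were 96.1% of all genes listed between strains, and each strain was grown as its own population.

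The 2nd pattern is the genes listed at 0 in 1 library. All 11 distinct loci wider than 50000 bp, with 17 of these 52 entries, are at 0 in 1 library of their pair, which is consistent with reads of such loci having been assigned to different gene models in the libraries. Of the 43 entries at 0 in a stress comparison, 4.65% are also listed for stress in the other strain, against 68.2% of the remaining entries. That 4.65% is a single gene, Y37E3.21, counted once in each strain. The genes at 0 had a low median of 1.35 FPKM in N2 and 1.04 FPKM in VZ1 in the other library, and of the genes above 0 with a higher value under 30 FPKM, 4 of 15 in N2 and 1 of 4 in VZ1 were listed in the other strain. Where the higher value was at least 10 FPKM, 1 of 8 genes at 0 in N2 and 1 of 2 in VZ1 were so listed, Y37E3.21 in each. All these numbers are too small to part level from a response to stress, which may lie behind some of the genes at 0.

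The 3rd pattern, a hypothesis on gene order, is that rising genes lie beside each other. Of 88 protein-coding genes that rose in N2, at loci with 1 name and above 0 in both libraries, 33 had another such gene within 5 protein-coding genes, against a median of 4 and a highest value of 17 in 10000 random sets of as many genes, so that chance placement is argued against. In VZ1 21 of 71 did, against at most 14. The VZ1 count is not a separate check, since 67 genes rose in both strains' stress tables. All 9 genes listed in N2 within 97.6 kb of chromosome IV rose, including dod-24, dod-17, C32H11.4 and F55G11.2. Genes between them that were not listed were not counted. The gene F55G11.6 of the 9 was at 0 in unstressed N2 and so is not among the 88. On chromosome II gst-20, gst-14, gst-12 and gst-16 rose within 16.2 kb. Both stretches were chosen around genes that rose, and 115 of all 151 genes listed in N2 rose. These counts are thus no further test of position. Random sets were drawn from all annotated protein-coding genes, so clusters of related genes, which may respond alike or share reads, are a candidate explanation that was not separated from position.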
